A study of Mus musculus with 9 samples.

How the data were processed

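RNA was measured in epidermal keratinocytes from the dorsal skin of mice of 3 genotypes, WT, Hmga2-/- and K5H2, with 3 animals each. Per the labels' protocols, the epidermis was separated after trypsin treatment, RNA was isolated with a micro-scale column kit, and stranded libraries were made from polyadenylated RNA. Trim Galore, STAR, DESeq2 and GRCm38 are listed in the submitters' processing notes, which give no tool version. Gene models were from Ensembl on mm10/GRCm38, per the file headers.

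The authors' deposited table lists 55536 genes. The 9 library columns hold normalized counts rounded to whole numbers, per the file headers, so they were handled as a score and not as raw read counts. A mean of the normalized counts over the libraries, also a score, was deposited beside them. The authors' comparisons were deposited as log2 fold changes with p-values and adjusted p-values, per the file headers. The authors' headers also state the criteria of a stringent call, which were not applied here. No column of per-sample values belonged to another series (0 such columns).

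What 1 read is worth in each library was estimated from genes listed above 0 in that library alone, where the deposited mean gives the unrounded value. Between 99.78% and 100% of those genes lay at whole multiples of one step, within 0.05 reads. The step was 0.723 in WT 3, the smallest, and 2.34 in Hmga2-/- 3, the largest. This gave approximate reads in genes of 36.7, 32.9 and 41.5 M in WT 1 to 3, 36.3, 28.1 and 15.4 M in Hmga2-/- 1 to 3, and 31.5, 29.5 and 31.5 M in K5H2 1 to 3. Most values are rounded, so single read counts were not recovered exactly and count intervals are not given.

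The comparison planned for raw counts could not be used on these values. The test planned for normalized values was used instead: limma-trend with empirical Bayes moderation, two-sided, on log2(value + 1). A gene was tested if its value was at least 10 in at least 3 libraries, which left 14695 genes. All 9 libraries entered one fit with a mean per genotype and no covariate, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Adjusted p values of genes come from this fit unless another source is named. Hmga2 was also compared with exact two-sided permutation tests, whose smallest possible p with 3 against 3 animals is 0.1.

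Gene lists were tested with camera at a preset correlation of 0.01 between genes, with a Benjamini-Hochberg adjustment over the 26 lists with at least 5 measured members. Of the 29 lists fixed before the data were examined, 764 of 766 names matched the table, 7 of them by another symbol. Camera with an estimated correlation and fry were run beside it. No list passed camera with an estimated correlation in any comparison: the smallest adjusted p was 0.723 for Hmga2-/- against WT, 0.564 for K5H2 against WT and 0.810 for K5H2 against Hmga2-/-. Calls within a list are also given after adjustment over the list alone.

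Genes were named by a rule set before the data were examined. It takes Hmga2, the 8 largest rises and 8 largest falls of each comparison among called genes whose replicates did not overlap and whose mean was at least 1 count per M in the higher group, without clone names. It also takes up to 3 called members of each list, 2 members of a list that passed with none called, and 10 genes of melanocyte signalling, cAMP response and UV response. Some were left out for length, and 1 result is not reported. Any other gene named is said to have been chosen after its values were seen.

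The fit was tested on simulated data in which 200 genes were changed, 50 at each of 4 fold sizes, and a list of 30 further genes was raised. For Hmga2-/- against WT (14560 genes) 44%, 74%, 86% and 88% of the genes changed 2-, 4-, 8- and 16-fold were recovered. For K5H2 against WT (14573 genes) the shares were 30%, 76%, 84% and 90%, and for K5H2 against Hmga2-/- (14551 genes) 32%, 72%, 80% and 88%. False calls made up 3.49%, 2.48% and 3.07% of calls. The noise was drawn for each gene separately, so deviations that many genes of a library share were absent. These rates may therefore not hold for the real libraries.

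Alternatives covered rescaling, filters, pseudocounts, the libraries in the fit, a minimum effect, robust moderation, the replicate number as a block, and each library left out in turn. Voom on approximate reads, a trimmed-mean rescaling and a fit without both WT 1 and Hmga2-/- 3 were added after seeing the data. The versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9 and BLAST+ 2.17.

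The labels describe 3 separate mice per genotype. No 2 libraries of a group were alike within counting noise: the median squared difference over counting variance ran from 4.90 to 28.8, against 0.455 for counting noise alone. Replicate numbers are not stated to pair animals. The K5H2 samples carry codes of a number series that no other library has (3 of 3 K5H2 libraries, 0 of the others), so genotype and any difference of colony or cohort cannot be separated.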

Results

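The transcriptomes of epidermal keratinocytes were profiled in 9 mice of 8 weeks of age, when dorsal hair follicles rest in telogen. Dorsal skin received 2 doses of 20 mJ/cm2 of UVB within 3 days and was taken 24 h after the last dose, and the epidermal sheet was lifted after a night on 0.25% trypsin. The animals were WT, Hmga2-/- or K5H2, with 3 mice per genotype. K5H2 is used here as the labels give it, without an explanation of the abbreviation. All 9 mice were exposed, so the comparisons are between genotypes after UVB and not between exposed and unexposed skin. The series title places the work in the context of Hmga2, cAMP signalling and the activation of melanocyte stem cells by UVB.

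Total normalized counts were 28.6, 30 and 30 M in WT 1 to 3, 30.6, 32.9 and 36.1 M in Hmga2-/- 1 to 3, and 28.3, 29.2 and 27.4 M in K5H2 1 to 3. The approximate depth behind them was lowest in Hmga2-/- 3, at 15.4 M reads in genes, and 28.1 to 41.5 M in the other 8 libraries. Mitochondrial genes held 0.279% of the normalized counts in Hmga2-/- 3 and 0.502% in Hmga2-/- 2, against 0.983% to 2.15% in the other 7. WT 1 and Hmga2-/- 3 lay at opposite ends of the first principal component, which held 36.6% of the variance, and the K5H2 libraries were set apart on the second, which held 23.3%.

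Hmga2, which encodes a chromatin protein that binds AT-rich DNA (chromosome 10, 120361275 to 120476469, GRCm38), was examined first. Its normalized counts were 346, 11 and 56 in WT, 3, 9 and 7 in Hmga2-/-, and 4, 11 and 0 in K5H2, giving means of 138 ± 182, 6.33 ± 3.06 and 5 ± 5.57 (SD, n = 3 each). The log2 difference was -3.18 (SE 1.17) for Hmga2-/- against WT, with every Hmga2-/- animal below every WT animal, and did not pass the limma test (adjusted p = 0.152). It was -3.98 (SE 1.17, adjusted p = 0.116) for K5H2 against WT and -0.81 (SE 1.17, adjusted p = 0.710) for K5H2 against Hmga2-/-. Exact two-sided permutation tests gave p = 0.1, the smallest that 3 against 3 animals allow, for Hmga2-/- against WT, 0.2 for K5H2 against WT and 0.7 for K5H2 against Hmga2-/-. The authors' deposited table gives log2 fold changes of -4.40 (adjusted p = 0.0377), -4.76 (adjusted p = 0.0210) and -0.36 (adjusted p = 0.924). WT 1 carried most of the WT signal: without it the log2 difference was -1.94 for Hmga2-/- and -2.74 for K5H2, while without WT 2 it was -4.36 and -5.17, the latter past the threshold (adjusted p = 0.0392). Which part of the gene is deleted is not given in the sources used here.

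**Figure D1:**
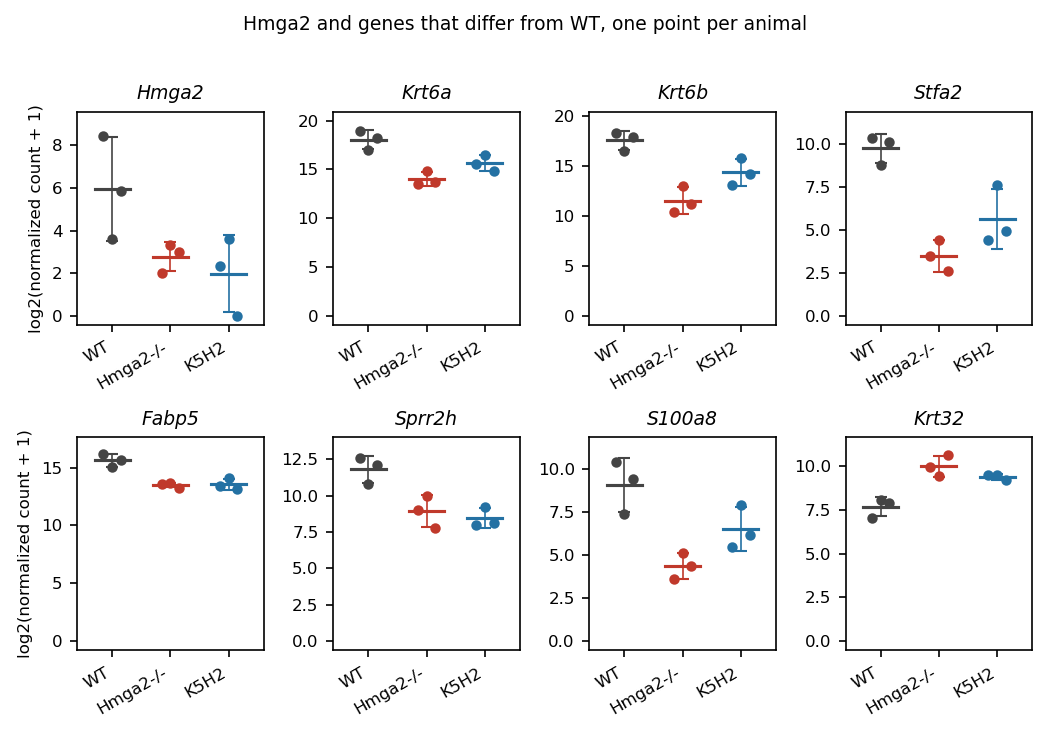
Normalized counts of Hmga2 and of 7 genes that differ from WT in Hmga2-/-, K5H2 or both, on a log2(normalized count + 1) axis, with 1 point per mouse, a bar at the mean of the log2 values and whiskers of 1 SD (n = 3). Krt6b lies between 94151 and 323404 in WT and between 1331 and 8108 in Hmga2-/-.

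The comparison of Hmga2-/- with WT addresses which keratinocyte transcripts differ between these genotypes after UVB. Genes that keratinocytes switch on in wounds and stressed skin were lower as a list in Hmga2-/- (camera adjusted p = 7.15e-15; adjusted p = 0.723 with an estimated correlation), with 7 of 32 members lower at the threshold, 1 higher and 24 not past it. Krt6b (chromosome 15, 101676023 to 101680287, GRCm38), a keratin of wounded epidermis, fell from 219474 ± 116114 in WT to 3930 ± 3654 in Hmga2-/- (SD, n = 3), a log2 fold change of -6.05 (SE 0.76, adjusted p = 0.0113). Its neighbour Krt6a (101689910 to 101694307) fell from 315340 ± 191758 to 18232 ± 9737 (log2 fold change -4.02, SE 0.55, adjusted p = 0.0180). Krt6a and Krt6b are close copies whose reads the counting could have divided between them. Stfa2, a stefin-type protease inhibitor of a family of close copies, fell from 952 ± 450 to 11.7 ± 7.64 (log2 fold change -6.27, SE 0.78, adjusted p = 0.0113). Of the 32 measured genes of stressed keratinocytes, 31 had negative log2 fold changes, with a median of -2.71. Those that fell include Krt16, Gjb2, Sprr1b and Sprr2a3, Arg1 rose, and adjusted over the list alone 23 fell and 1 rose. Krt16, Gjb2, Sprr1b, Sprr2a3 and Arg1 were chosen after their values were seen. The list's median per library, relative to each gene's mean over the libraries, was 2.69, 1.06 and 1.83 in WT and -0.90, 0.04 and -1.95 in Hmga2-/-.

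The lists of cell division genes and of sebaceous gland genes also passed camera downward in Hmga2-/- at the preset correlation, and neither passed with an estimated one. Among 40 division genes 36 had negative log2 fold changes (median -0.45). The mitotic genes Bub1, at 519 ± 136 in WT and 231 ± 38.9 in Hmga2-/- (log2 fold change -1.15, adjusted p = 0.0473), and Tpx2 (-0.81, adjusted p = 0.0495) fell at the threshold, and 16 fell when adjusted over the list alone. The division list passed camera (adjusted p = 4.55e-08; adjusted p = 0.723 with an estimated correlation). Of 27 sebocyte genes 23 had negative values (median -0.83), 14 fell when adjusted over the list alone, and the list passed camera (adjusted p = 8.66e-07; adjusted p = 0.723 with an estimated correlation). Fabp5, a fatty acid binding protein that keratinocytes also make, fell from 52959 ± 19823 to 11544 ± 1520 (log2 fold change -2.14, SE 0.30, adjusted p = 0.0182). It shares sequence with the pseudogene Gm6166, which was chosen after its values were seen. WT 1 had the highest median of the stress, division and sebocyte lists (2.69, 0.46 and 1.45), and Hmga2-/- 3, the shallowest library, the lowest (-1.95, -0.37 and -0.86).

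The lists of Langerhans cells, epidermal T cells, dermal fibroblasts and immediate early genes passed camera upward at the preset correlation, and none with an estimated one. All 18 genes of Langerhans cells and class II antigen presentation had positive log2 fold changes (median 0.69), and the list passed camera (adjusted p = 0.00416; adjusted p = 0.723 with an estimated correlation), with no member past the threshold. H2-Eb1 was at 2883 ± 1829 in WT and 6434 ± 2225 in Hmga2-/- (adjusted p = 0.141), and Cd74 at 4528 ± 3154 and 10376 ± 4475 (adjusted p = 0.162). Of 22 epidermal T cell genes 19 had positive values, 0 past the threshold (median 0.49; camera adjusted p = 0.0320; adjusted p = 0.734 with an estimated correlation), among them Cd3d (log2 fold change 1.19, adjusted p = 0.187) and Thy1 (0.83, adjusted p = 0.170). Both immune lists were lowest in WT 1, with medians of -1.42 and -1.31. Without WT 1 their adjusted p values were 0.247 and 0.953, without Hmga2-/- 2 they were 0.0634 and 0.130, and the T cell list also missed the threshold without K5H2 3 (0.0521). Dermal fibroblast genes had positive values in 10 of 13 members (median 0.87; camera adjusted p = 0.00840; adjusted p = 0.723 with an estimated correlation). None of them passed over all genes and 5 rose when adjusted over the list alone. The collagen gene Col1a2 was at 17, 23 and 15 in WT and 360, 183 and 94 in Hmga2-/- (adjusted p = 0.0808), and Sparc at 701 ± 208 and 1254 ± 152 (adjusted p = 0.0793). Immediate early and heat shock genes, which tissue dissociation also raises, had positive values in 21 of 29 members (median 0.25; camera adjusted p = 0.00416; adjusted p = 0.723 with an estimated correlation), with Klf2 called (log2 fold change 1.79) and 8 genes adjusted over the list alone. This list missed the threshold without Hmga2-/- 2 (adjusted p = 0.0634).

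Other single genes differed strongly. Lrat, which esterifies retinol, was at 936, 152 and 216 in WT and 0, 6 and 2 in Hmga2-/- (log2 fold change -6.83, SE 0.83, adjusted p = 0.0113). Large falls were also called for Cdhr1 (-6.48), Cemip (-5.45), which takes part in hyaluronan breakdown, the homeobox gene Pitx1 (-5.07), the protease gene Tmprss11b (-4.92) and Cntfr (-4.86). In Hmga2-/- Cdhr1 was at 4, 25 and 0, Cemip at 1, 0 and 7, and Pitx1 at 6, 0 and 0. Tmprss11b was at 11, 12 and 2 and Cntfr at 3, 7 and 0. The sizes of these falls and that of Lrat therefore depend on the pseudocount. WT 1 had the highest WT value of each of these genes. S100a8, an alarmin of inflamed epidermis, fell from 726 ± 594 to 21 ± 11.1 (log2 fold change -4.71), the growth factor gene Nrg1 from 622 ± 691 to 22 ± 5.20 (-4.15), and the cystine transporter gene Slc7a11 from 248 ± 151 to 40 ± 7.81 (-2.38), and the falls of Fbln1 (-1.57) and Bhlhe40 (-1.14) were smaller. The hair keratin genes Krt32 (2.31) and Krt33a (3.44), Fam180a (2.81), Spock2 (2.26), Camk2n1 (2.21), the adenosine receptor gene Adora1 (2.08), the prostaglandin D synthase gene Ptgds (2.01) and Ccn2 (1.32) rose.

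In all, limma called 107 of 14695 genes, 16 higher and 91 lower in Hmga2-/-, and 3478 had an unadjusted p under 0.05. Replicates of the 2 groups did not overlap in 29.7% of genes, where chance gives 10% on average. Genes of a library vary together, and how far chance alone moves this share was not tested. The authors' deposited table has 1154 genes with an adjusted p under 0.05, 458 higher and 696 lower, and 106 of the 107 genes called here are among them with the same sign. The number of called genes depended on single animals: it was 23 without WT 1, 482 without WT 2, 1 without WT 3, 11, 46 and 7 without Hmga2-/- 1, 2 and 3, and 57 and 48 without K5H2 2 and 3, which enter through the shared spread. Without both WT 1 and Hmga2-/- 3 limma called 0 genes, with 1156 at an unadjusted p under 0.05.

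**Figure D2:**
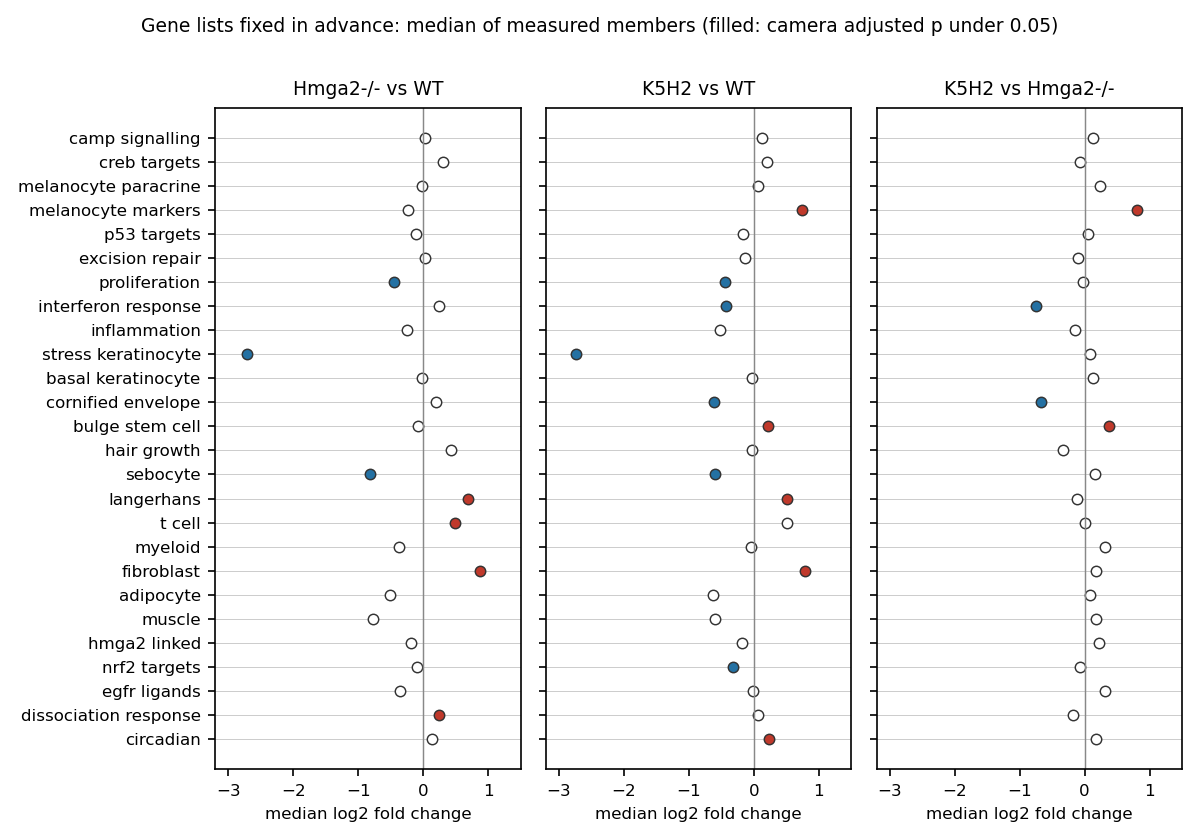
Median log2 fold change of the measured members of each of 26 gene lists in the 3 comparisons, with 1 point per list, filled where camera gave an adjusted p under 0.05 at the preset correlation. The list of stressed keratinocytes lies at -2.71 for Hmga2-/- and -2.74 for K5H2 against WT, and at 0.09 for K5H2 against Hmga2-/-.

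The comparison of K5H2 with WT asks the same of K5H2. Genes of stressed keratinocytes were lower as a list here too, with negative log2 fold changes in 30 of 32 members (median -2.74). At the threshold 9 fell and 1, Arg1, rose, and adjusted over the list alone 24 fell and 1 rose (camera adjusted p = 9.80e-16; adjusted p = 0.564 with an estimated correlation). Sprr2h, a precursor of the cornified envelope, fell from 4069 ± 2186 in WT to 379 ± 192 in K5H2 (SD, n = 3; log2 fold change -3.36, SE 0.57, adjusted p = 0.0287). Lce3d fell from 330 ± 236 to 18.3 ± 4.62 (-3.91, SE 0.72, adjusted p = 0.0373), and Stfa2 (-4.11), Lce3f (-3.82) and Sprr2e (-3.21) fell. The Sprr2, Lce3 and Stfa genes are families of close copies, so the division of reads among members is uncertain. The median of the list per library was -1.60, 0.00 and -0.85 in K5H2 1 to 3. Division genes had a median of -0.45, with 36 of 40 negative, 0 past the threshold over all genes and 16 lower when adjusted over the list alone (camera adjusted p = 4.82e-10; adjusted p = 0.564 with an estimated correlation). Plk1, a mitotic kinase gene, was at 1161 ± 287 and 525 ± 39.6 (adjusted p = 0.0624), and Ccne1 at 543 ± 137 and 242 ± 43.9 (adjusted p = 0.0722). Sebocyte genes had a median of -0.59 with 22 of 27 negative and 8 lower when adjusted over the list alone (camera adjusted p = 3.62e-05; adjusted p = 0.564 with an estimated correlation), and Fabp5 fell from 52959 ± 19823 to 12675 ± 4325 (log2 fold change -2.05).

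The lists of the differentiated layers, the interferon response and the antioxidant response passed camera downward in K5H2 at the preset correlation, and none with an estimated one. Of 47 genes of the spinous, granular and cornified layers 40 had negative values (median -0.61), with 0 past the threshold and 5 lower when adjusted over the list alone (camera adjusted p = 0.000118; adjusted p = 0.584 with an estimated correlation). The kallikrein gene Klk8 was at 5771 ± 491 in WT and 2930 ± 667 in K5H2 (adjusted p = 0.0542), and the transglutaminase gene Tgm3 at 3639 ± 499 and 2227 ± 494 (adjusted p = 0.0677). Without K5H2 1, whose list median was the lowest at -1.09, the list missed the threshold (adjusted p = 0.127). Interferon-stimulated genes were negative in 20 of 29, 0 past the threshold (median -0.43; camera adjusted p = 0.0251; adjusted p = 0.584 with an estimated correlation), with Zbp1 at 24 ± 6.08 and 5 ± 3.61 (adjusted p = 0.135) and Ifi35 at 735 ± 112 and 511 ± 82.6 (adjusted p = 0.149). This call was lost without WT 2 (0.290), WT 3 (0.186), K5H2 1 (0.108) or K5H2 3 (0.0828). NRF2 targets were negative in 14 of 20 (median -0.31; camera adjusted p = 0.0193; adjusted p = 0.564 with an estimated correlation), with 1 called fall, Srxn1, from 1548 ± 313 to 754 ± 83.8 (log2 fold change -1.02), and adjusted over the list alone 5 fell and 2 rose. Without WT 1 the NRF2 list missed the threshold (0.0824).

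The melanocyte, bulge, Langerhans, fibroblast and clock lists passed camera upward in K5H2 at the preset correlation, and none with an estimated one. Melanocyte lineage genes were positive in 10 of 11 (median 0.74; camera adjusted p = 0.0193; adjusted p = 0.564 with an estimated correlation), 0 past the threshold and 1 adjusted over the list alone. Mitf, the regulator of the melanocyte lineage, was at 129 ± 20.4 in WT and 275 ± 47.9 in K5H2 (log2 fold change 1.09, adjusted p = 0.0698), and the pigment gene Pmel at 38.3 ± 8.14 and 85 ± 48.5 (adjusted p = 0.335). The melanocyte call was lost without WT 3 (0.0913) or K5H2 3 (0.108). Genes of hair follicle bulge stem cells were positive in 13 of 20 (median 0.21; camera adjusted p = 0.0128; adjusted p = 0.573 with an estimated correlation), and adjusted over the list alone 6 rose and 1 fell. Ccn2, a matrix-associated growth regulator, rose from 318 ± 100 to 1873 ± 511 (log2 fold change 2.56, SE 0.24, adjusted p = 0.00132), Fgf18 rose from 200 ± 28.7 to 523 ± 149 (1.36, adjusted p = 0.0373), and Fbln1 fell (-1.18). The bulge call was lost without WT 2 (0.0757). Langerhans genes were positive in 17 of 18, 0 past the threshold (median 0.50; camera adjusted p = 0.00727; adjusted p = 0.584 with an estimated correlation), with Cd83 at 39.3 ± 20.4 and 77.7 ± 18.7 (adjusted p = 0.223) and Csf1r at 559 ± 312 and 1069 ± 399 (adjusted p = 0.242). The Langerhans call was lost without WT 1 (0.484) or K5H2 3 (0.0760). Fibroblast genes were positive in 10 of 13 (median 0.78; camera adjusted p = 0.00447; adjusted p = 0.564 with an estimated correlation). Col1a2, at 1069, 236 and 80 in K5H2 and 15 to 23 in WT, and Sparc, at 1404 ± 116 and 701 ± 208, rose at the threshold (log2 fold changes 3.85 and 1.04), and 6 rose when adjusted over the list alone. Circadian clock genes were positive in 13 of 18 (median 0.23; camera adjusted p = 0.0160; adjusted p = 0.564 with an estimated correlation), with 6 higher when adjusted over the list alone. Per2, a repressor in the clock, rose from 385 ± 65.6 to 788 ± 151 (log2 fold change 1.03, SE 0.19, adjusted p = 0.0376), and the clock call was lost without K5H2 3 (0.0609).

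Zbtb16, a transcription factor gene, rose from 222 ± 92.4 to 2234 ± 486 (log2 fold change 3.40, SE 0.49, adjusted p = 0.0146), and Prune2 from 8 ± 5.20 to 105 ± 39.9 (3.64, adjusted p = 0.00758). Of the cAMP list 1 of 39 measured genes was called, the adenylyl cyclase gene Adcy7, from 186 ± 28.2 to 383 ± 63.6 (1.03, adjusted p = 0.0424). Of the CREB list 1 of 27 was called, the salt-inducible kinase gene Sik1, from 1518 ± 283 to 2983 ± 480 (0.98, adjusted p = 0.0424). Sesn1, a p53 target, rose from 1045 ± 220 to 2447 ± 98.2 (1.25, SE 0.16, adjusted p = 0.00699). It was the 1 called gene of 30 p53 targets, of which 21 had negative log2 fold changes. The defensin gene Defb14 (-4.64), the retinaldehyde dehydrogenase gene Aldh1a3 (-3.54), Pi15 (-3.72), Tmprss11b (-3.72) and Cidec (-3.05), a lipid droplet gene, fell. Trim12a, a member of a TRIM gene cluster (chromosome 7, 104299894 to 104315466, GRCm38), was at 76, 218 and 212 in WT and listed at 0 in all K5H2 libraries, while Ccnb1ip1 (chromosome 14, 50789248 to 50807732) was listed at 0 in all WT libraries and at 68, 16 and 19 in K5H2. Processed pseudogenes made up much of the largest rises: Rpl34-ps1 went from 38 ± 9.85 to 1298 ± 1030, Hmgb1-ps7 from 17 ± 5.57 to 422 ± 148 and Tma7-ps from 16.3 ± 6.51 to 324 ± 156, and Rpl31-ps15 was listed at 0 in WT and at 17, 44 and 34 in K5H2. These pseudogenes are near copies of expressed genes, so their values are uncertain.

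**Figure D3:**
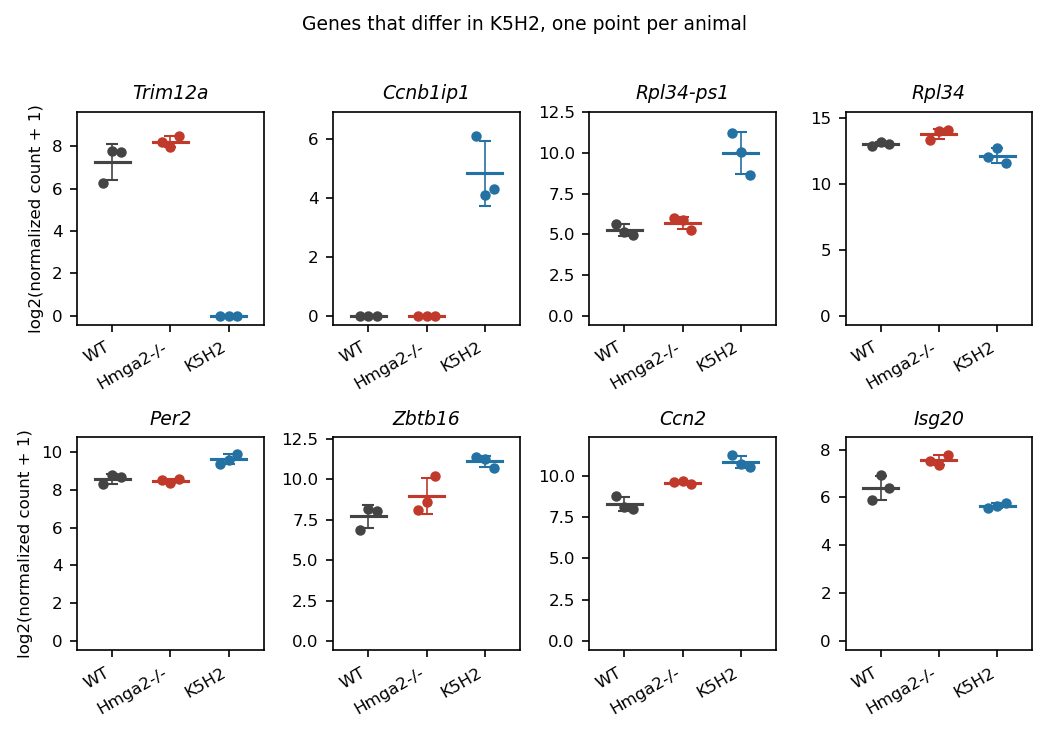
Normalized counts of 8 genes that differ in K5H2 from WT, Hmga2-/- or both, on a log2(normalized count + 1) axis, with 1 point per mouse, a bar at the mean of the log2 values and whiskers of 1 SD (n = 3). Trim12a is listed at 0 in all K5H2 mice and between 76 and 358 in the others, and the values of Rpl34-ps1 depend on how reads shared with Rpl34 were counted.

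For K5H2 against WT limma called 188 of 14695 genes, 96 higher and 92 lower, of which 18 are pseudogenes, and 2652 had an unadjusted p under 0.05. Replicates did not overlap in 26.9% of genes, against 10% on average by chance, with the same limit. The authors' deposited table has 986 genes with an adjusted p under 0.05, 467 higher and 519 lower, and includes all 188 with the same sign. Called genes numbered 51, 307 and 17 without WT 1, 2 and 3, and 21, 48 and 32 without K5H2 1, 2 and 3. The codes of the K5H2 samples belong to a separate number series, so a difference of cohort cannot be told from genotype.

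K5H2 was then compared with Hmga2-/-, which also tests whether these groups differ from WT by unequal amounts. Genes of stressed keratinocytes did not differ detectably, with a median log2 fold change of 0.09 and 17 of 32 positive (camera adjusted p = 0.723). Melanocyte lineage genes had positive log2 fold changes in 11 of 11 members (median 0.80; camera adjusted p = 0.0122; adjusted p = 0.810 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone. Tyrp1 was at 41 ± 29.1 in Hmga2-/- and 122 ± 56.1 in K5H2 (SD, n = 3; adjusted p = 0.159), and Kit at 33, 76 and 14 in Hmga2-/- and 99, 81 and 105 in K5H2 (adjusted p = 0.160). The melanocyte call was lost without Hmga2-/- 3 (0.0953), K5H2 1 (0.0978) or K5H2 3 (0.0801). Bulge genes were positive in 17 of 20, 0 past the threshold (median 0.37; camera adjusted p = 0.00169; adjusted p = 0.810 with an estimated correlation), 5 of them higher when adjusted over the list alone. Ccn2 was at 771 ± 40.9 and 1873 ± 511 (log2 fold change 1.25, adjusted p = 0.0544) and Angptl7 at 82.3 ± 49.1 and 375 ± 168 (2.22, adjusted p = 0.0699). The bulge call was lost without Hmga2-/- 3 (0.0743) or K5H2 1 (0.0978).

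Interferon-stimulated genes had negative log2 fold changes in K5H2 against Hmga2-/- in 23 of 29 members, 0 of them past the threshold over all genes (median -0.74; camera adjusted p = 0.000176; adjusted p = 0.810 with an estimated correlation). Adjusted over the list alone 11 fell. Ifi27l2a was at 118 ± 7.55 and 40.7 ± 14.8 (log2 fold change -1.57, adjusted p = 0.112) and Ifi35 at 807 ± 36.3 and 511 ± 82.6 (-0.67, adjusted p = 0.112). Isg20, an interferon-stimulated exonuclease gene outside the list, fell from 189 ± 27.2 to 49.7 ± 4.04 (-1.90, SE 0.29, adjusted p = 0.0192). Genes of the differentiated layers were negative in 37 of 47, 0 past the threshold (median -0.66; camera adjusted p = 0.000159; adjusted p = 0.888 with an estimated correlation), with 1 lower when adjusted over the list alone. Klk8 was at 6418 ± 1599 and 2930 ± 667 (-1.12, adjusted p = 0.0544) and Klk5 at 11984 ± 3159 and 5964 ± 1505 (adjusted p = 0.138), and the call was lost without K5H2 1 (0.255).

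Per2 rose from 355 ± 28.1 in Hmga2-/- to 788 ± 151 in K5H2 (log2 fold change 1.13, SE 0.19, adjusted p = 0.0338), and Creg2 (3.51), Rfx3 (3.06), a transcription factor gene of ciliated cells, and Prune2 (2.96) rose. Trim34a fell from 108 ± 26.9 to 16 ± 4.36 (-2.68), and Trim12a, in the same cluster, was at 298, 247 and 358 in Hmga2-/- and listed at 0 in K5H2. The long noncoding RNA gene Cep83os (-2.92) and Ang (-2.17) also fell, as did Rpl34, a ribosomal protein gene, from 14631 ± 3701 to 4776 ± 1855 (-1.65, SE 0.27, adjusted p = 0.0281), and Ndufs5, a subunit gene of respiratory complex I, from 1368 ± 230 to 463 ± 136 (-1.60, adjusted p = 0.0175). Rpl34 and Ndufs5 have near-identical pseudogenes, Rpl34-ps1 (52 ± 13.2 and 1298 ± 1030) and BC002163 (39 and 157, means of 3), which rose, so their reads may be divided differently (BC002163 was chosen after its values were seen). Hmgb1-ps7 (5.17), Rpl31-ps15 (4.60, from values of 0, 1 and 0 in Hmga2-/-) and Tma7-ps (3.92) rose and Rps19-ps6 (-5.88) fell. Rps19-ps6 was at 4110, 2516 and 4802 in Hmga2-/-, and at 51, 78 and 58 in K5H2. In WT it was at 68, 1807 and 1599, so WT 1 lay within the K5H2 values. Ccnb1ip1 was listed at 0 in Hmga2-/- and at 68, 16 and 19 in K5H2. In this comparison limma called 73 of 14695 genes, 53 higher and 20 lower, with 3099 at an unadjusted p under 0.05. Replicates did not overlap in 26.4% of genes, against 10% on average by chance, with the same limit. Pseudogenes made up 28.8% of the called genes (21) and 4.14% of those tested (two-sided Fisher's exact test, p = 9.17e-13). The authors' deposited table has 626 genes with an adjusted p under 0.05, 349 higher and 277 lower, and includes all 73 with the same sign. Called genes numbered 213 without WT 1, 40 without WT 3, 33 and 34 without Hmga2-/- 2 and 3, and 29, 32 and 19 without K5H2 1, 2 and 3.

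The overlap of the comparisons with WT shows how far the changes were shared. Both called 34 genes in the same direction, 7 higher and 27 lower, and 0 in opposite directions. Independent lists of these sizes would share 0.105 higher and 0.570 lower genes. The shared rises include Ccn2, Krt32, Arg1, Adora1, Ptgds and Lgr6, a stem cell receptor gene, and the shared falls include Stfa2, Tmprss11b, Pi15, Aldh1a3, Fabp5, Fbln1, Sprr1b, the hyaluronan synthase gene Has3, Elk3 and Klk13. Lgr6, Has3, Elk3 and Klk13 were chosen after their values were seen. Across genes, which are not independent replicates, log2 fold changes correlated at 0.547, and simulated unchanged groups gave 0.354 on average (-0.60 to 0.92 in 95% of draws). In each draw new WT libraries served both comparisons, mixed at random from the deviations of the WT animals from their mean. The covariance was 0.261 against a simulated 0.0699 (-0.08 to 0.28), a difference of 0.191. Of 100 simulated draws 96 shared no call and 4 shared at least as many, up to 3392. The 3 WT libraries cannot be split into groups of 2, so part of the excess may come from the shared controls. Between K5H2 and Hmga2-/- 2 of the shared genes, AI506816 and Gm49428, also passed, and were likewise chosen after their values were seen. Shared calls numbered 4 without WT 1, 156 without WT 2 and 0 without WT 3, 5, 17 and 4 without Hmga2-/- 1, 2 and 3, and 3, 9 and 6 without K5H2 1, 2 and 3.

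The single genes fixed in advance for melanocyte signalling, cAMP response and UV response did not pass in any comparison. Nrg1, from the list of keratinocyte signals to melanocytes, was not among them and was called lower in Hmga2-/- against WT (limma adjusted p = 0.0326). Pomc, the precursor of melanocyte-stimulating hormone, was at 1 to 8 normalized counts per library and its receptor gene Mc1r at 0 to 6, too low to test, and Edn3 and the agouti gene were listed at 0 in all 9 libraries. Kitl, the ligand of Kit, was at 984 ± 127 in WT, 840 ± 109 in Hmga2-/- and 980 ± 167 in K5H2. Edn1 was at 74 ± 23.3, 94.3 ± 9.61 and 113 ± 11.5, and Cdkn1a, a p53 target, at 28160 ± 4302, 34174 ± 550 and 27264 ± 3190. Among genes that respond to cAMP, Nr4a1 was at 95.7 ± 9.07 in WT, 340 ± 236 in Hmga2-/- (log2 fold change 1.60, adjusted p = 0.111) and 347 ± 161 in K5H2 (1.74, adjusted p = 0.0890). Crem was at 138 ± 7.02, 124 ± 19 and 107 ± 5.29, and Pde4b, which breaks down cAMP, at 470 ± 80.9, 343 ± 40.7 and 508 ± 40.7.

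The remaining lists passed camera in no comparison, and their medians follow in the order Hmga2-/- against WT, K5H2 against WT and K5H2 against Hmga2-/-. Genes of cAMP production and breakdown had medians of 0.03, 0.12 and 0.13 over 39 members (camera adjusted p = 0.519, 0.0522 and 0.463), and CREB-responsive genes 0.30, 0.19 and -0.07 over 27 members (0.146, 0.0778 and 0.974). Keratinocyte signals to melanocytes had medians of -0.02, 0.06 and 0.24 over 24 members (0.711, 0.379 and 0.189), and the directional fry test passed for this list between K5H2 and Hmga2-/- (adjusted p = 0.0359), its only pass in the 3 comparisons. In Hmga2-/- against WT 1 member of this list, Nrg1, was called lower, and 2 fell when adjusted over the list alone. In K5H2 against WT 0 were called, and adjusted over the list alone 2 rose and 1 fell. The cAMP list passed camera for K5H2 against WT without WT 2 (adjusted p = 0.0490), K5H2 1 (0.0255) or K5H2 2 (0.0266) and with upper-quartile (0.0491) or trimmed-mean rescaling (0.0499). With all libraries it had adjusted p = 0.564 with an estimated correlation. The CREB list passed for Hmga2-/- against WT without Hmga2-/- 3 (0.0282) or both WT 1 and Hmga2-/- 3 (0.0115), and for K5H2 against WT without K5H2 3 (0.0461) or with the replicate block (0.0406), all upward. With all libraries it had adjusted p = 0.723 and 0.564 with an estimated correlation. The CREB list shares several genes, Nr4a1 among them, with the list of immediate early genes that tissue dissociation also raises. These lists are therefore not separate evidence. Medians were -0.10, -0.16 and 0.05 for p53 targets, 0.03, -0.13 and -0.10 for excision repair, -0.25, -0.52 and -0.15 for inflammation, -0.02, -0.03 and 0.13 for basal keratinocytes, and 0.42, -0.04 and -0.33 for hair growth. They were -0.38, -0.04 and 0.31 for myeloid cells, -0.51, -0.63 and 0.08 for adipocytes, -0.77, -0.60 and 0.18 for skeletal muscle, -0.19, -0.18 and 0.22 for Hmga2-linked growth genes, and -0.35, -0.01 and 0.31 for EGFR ligands and feedback genes. Hair growth genes passed upward for Hmga2-/- against WT without Hmga2-/- 3 (0.00677) or both WT 1 and Hmga2-/- 3 (0.00451), inflammation genes downward for K5H2 against WT without K5H2 2 (0.0466), and EGFR genes upward for K5H2 against Hmga2-/- without K5H2 3 (0.0195). With all libraries these had adjusted p = 0.723, 0.564 and 0.815 with an estimated correlation. Lists that passed elsewhere gained a call for interferon genes upward in Hmga2-/- against WT without WT 2 (0.0181), WT 3 (0.0104) or Hmga2-/- 3 (0.00646), for T cell genes upward in K5H2 against WT without WT 2 (0.000727) or K5H2 1 (0.0107), and for immediate early genes upward in K5H2 against WT without K5H2 3 (0.0399) and downward in K5H2 against Hmga2-/- without Hmga2-/- 1 (0.0113) or K5H2 2 (0.0111). With all libraries these had adjusted p = 0.734, 0.727, 0.660 and 0.888 with an estimated correlation. Endothelial cells (4 measured genes), red blood cells (3) and sex-linked genes (4) had too few members for the test, with medians of 0.25, 0.17 and 0.30, of 0.41, 0.83 and 0.10, and of -0.09, 0.15 and 0.44. Mean, median and camera direction differed in sign for basal keratinocytes against WT in both groups, for hair growth and EGFR ligands in K5H2 against WT, and for CREB-responsive, T cell, adipocyte and NRF2 genes in K5H2 against Hmga2-/-. The mixed fry test, which asks whether genes of a list change in either direction, passed for 19, 15 and 7 of 26 lists. When the 6 libraries of a comparison were regrouped against genotype, camera passed up to 11 lists, and the true groupings passed 7, 11 and 4, so the number of passing lists does not set genotype apart from other splits.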

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

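The tests of other splits of the libraries were planned, while the tests on pseudogene parents, on genes listed at 0, on the stress list and on fibroblast genes, and the genes named in them, were chosen after the results were seen. The genes in this paragraph stood out because the effect of K5H2 against WT differed from that of Hmga2-/- against WT, in the limma test of the difference (adjusted p under 0.05). That test is the comparison of K5H2 with Hmga2-/- reported above. The values repeat it, and several of the genes had been named because they were called in it. The difference on the log2 scale was 5.17 for Hmgb1-ps7, 4.60 for Rpl31-ps15, 4.29 for Rpl34-ps1, 3.92 for Tma7-ps, 3.51 for Creg2, 3.06 for Rfx3, 2.96 for Prune2 and 1.13 for Per2. It was -5.88 for Rps19-ps6, -2.92 for Cep83os, -2.68 for Trim34a, -2.17 for Ang, -1.90 for Isg20, -1.65 for Rpl34 and -1.60 for Ndufs5. For Ccnb1ip1 (4.84) and Trim12a (-8.22), listed at 0 in whole groups, the fitted value depends on the pseudocount and is no fold. The same limit holds for Rpl31-ps15, listed at 0 in all WT libraries and at 0, 1 and 0 in Hmga2-/-.

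All 21 pseudogenes called between K5H2 and Hmga2-/- had a parent at least 90% identical. Of 17 tested parents 3, Rpl34, Rpl29 and Ndufs5, were called in the opposite direction. Among 12968 protein-coding genes 37 were called at all (Fisher's exact test for the difference, p = 1.41e-05). Since 18 of the 21 pseudogenes rose, a fall of parents for any reason mostly counted as opposite. The genes were also not matched for expression, so the test cannot decide whether reads were shared. Between Hmga2-/- and K5H2 the called pseudogenes gained at most 0.131 of what the parents lost. This argues against a move of reads to these pseudogenes as the whole of the 3 falls. Reads moved to copies that were not called, or left uncounted, were not tested. Rps19-ps6, Rpl21-ps8 and Gm6548 fell. Their parents Rps19 (-0.75), Rpl21 (-1.21) and Eef1a1 (-0.37) had values of the same sign, and 0 of the 3 were called. Tested parents of pseudogenes that rose were nearly all negative too, except Fabp5 (0.09). The shared sign therefore cannot tell whether reads were exchanged. Taking genes at 0 in 1 group and at 10 or more in all other libraries, or the reverse, Trim12a and Gm42047 were off and Ccnb1ip1, Gm35082, Gm12813 and Gm12666 on only in K5H2, 6 genes, against 0 for WT or Hmga2-/-; a strain sequence difference between the K5H2 animals and the others and the K5H2 genotype itself cannot be told apart, since this count is the observation itself and all 3 K5H2 libraries carry codes of a number series of their own.

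Genes of stressed keratinocytes were lower as a list in Hmga2-/- and K5H2 against WT (adjusted p = 0.723 and 0.564 with an estimated correlation), with Stfa2 and Sprr1b called lower and Arg1 higher in both. A single WT library as the whole cause is argued against by a median log2 fold change of -2.25 without WT 1, and the low depth of Hmga2-/- 3 by -2.27 without that library, against -2.71 with all. A state of the 3 WT animals shared by both comparisons cannot be told apart from an effect of genotype, because K5H2 against Hmga2-/- had a median of 0.086 and only these 3 WT animals were profiled. The genotypes may therefore lower this response, or the WT animals may have been more strongly activated. No unexposed animals were profiled, so whether UVB had raised these genes was not tested.

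Fibroblast genes were higher as a list in Hmga2-/- and K5H2 against WT (adjusted p = 0.723 and 0.564 with an estimated correlation), with medians per library of -0.93, -0.20 and -0.51 in WT, 0.65, 0.69 and -0.01 in Hmga2-/- and 1.03, 0.13 and -0.29 in K5H2. Whether dermal fibroblast RNA in the Hmga2-/- and K5H2 sheets raised Col1a1, Col1a2, Col3a1 and Dcn was not settled: Col1a2, Col3a1 and Dcn differed from Col1a1 by at most 1.33 standard errors, but these errors were wide, and in K5H2 1 and 2 Col1a1 was at 1389 and 271 and Dcn at 34 and 39. For Sparc the same explanation stays open: in 4 of the 6 Hmga2-/- and K5H2 libraries it added more counts than Col1a1 and Col1a2 together, and the WT sheets, with Col1a2 at 15 to 23, already held 701 ± 208 of it (SD, n = 3). A change of genotype in fibroblasts was not tested.

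Other splits of the libraries were compared with the true grouping. For Hmga2-/- against WT, 1 of 10 splits, the true one, gave as many as 107 genes, and the highest other gave 1. For K5H2 against WT the true split alone gave 188 (1 of 10, highest other 0), and for K5H2 against Hmga2-/- 73 (1 of 10, highest other 0). With 10 splits no share under 0.05 can be reached. Gene lists did not set the true grouping apart: as many lists as its 7, 11 and 4 passed in 6, 2 and 8 of 10 splits, and the highest other count was 11 in each comparison. The 34 shared calls were reached by 1 of 100 regroupings of the 9 libraries, the true one, and the highest other gave 0. This argues against arbitrary groups but says little about the sharing itself. Other splits called at most 1 gene in a comparison, so hardly any call could be shared. The shared WT libraries are not excluded as a source. Of 100 simulated draws without change, with simulated WT libraries that served both comparisons, 4 shared at least as many calls. The observed correlation of 0.547 and covariance of 0.261 lay within the simulated ranges.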

How the results depend on the processing

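Voom on approximate reads and the fit without both WT 1 and Hmga2-/- 3 were tests chosen after seeing the data. Called genes numbered 107 for Hmga2-/- against WT, 188 for K5H2 against WT and 73 for K5H2 against Hmga2-/-, 34 were shared by the comparisons with WT, and 7, 11 and 4 lists passed. With only the 6 libraries compared the counts were 38, 103 and 65, with 7 shared; the cause was not tested. Against a minimum fold of 1.2 (treat) they were 47, 53 and 44, with 7 shared, a stricter test by construction. Without a filter they were 1, 12 and 9, with 0 shared and 4133, 3442 and 3679 genes at an unadjusted limma p under 0.05. That fit is unreliable, because limma warned that more than 0.5 of the residual variances were 0. The replicate block moved K5H2 against WT to 120, a pseudocount of 5 moved the shared calls to 58, and voom gave 23 and 302 against WT with 15 shared; the cause was not tested. Without both WT 1 and Hmga2-/- 3 the counts were 0 (1156 at an unadjusted limma p under 0.05), 74 and 42, with 0 shared, in a fit of fewer libraries. Leaving out 1 library at a time gave 1 (without WT 3) to 482 (without WT 2) genes for Hmga2-/- against WT, 17 (without WT 3) to 307 (without WT 2) for K5H2 against WT, 19 (without K5H2 3) to 213 (without WT 1) for K5H2 against Hmga2-/-, 0 to 156 shared calls, and 4 to 10, 9 to 13 and 1 to 5 lists. The Hmga2 difference ran from -4.36 to -1.94 for Hmga2-/- against WT, from -5.17 (past the threshold, without WT 2) to -2.74 for K5H2 against WT, and from -1.61 to 0.18 (without K5H2 3) for K5H2 against Hmga2-/-. With an estimated correlation 0, 0 and 0 lists passed, and with directional fry 0, 0 and 1. Of the 27, 30 and 17 named genes called, 0, 5 and 5 passed in every leave-one-out fit, Rpl34-ps1, Hmgb1-ps7, Tma7-ps and Trim12a in both comparisons of K5H2, and 0 changed sign under any setting. Rescaling moved no count by over 1.5 times, but its factors were only 0.967 to 1.02. The deposited values were already normalized, so little change was possible. Libraries of different groups with the same replicate number correlated at -0.217 to 0.209 after the group means were removed. Those with different numbers correlated at -0.262 to 0.239, so a pairing of animals was neither shown nor excluded. The planned edgeR and DESeq2 fits were not run because the values used here are not raw counts. Weights per library were tried and not used, since their estimate did not converge and gave WT 3 a weight of 53.5. The shallowest library, Hmga2-/- 3 (15.4 M reads in genes), limits what can be seen among low genes.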

Other observations

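The genes in this paragraph and the glucocorticoid tests below were chosen after the values were seen. The hyaluronan synthase gene Has3 fell from 879 ± 780 in WT to 29.7 ± 3.51 in Hmga2-/- (SD, n = 3; limma adjusted p = 0.0151) and to 85.3 ± 43.1 in K5H2 (adjusted p = 0.0385). Cemip fell in Hmga2-/- (adjusted p = 0.0221) and had a log2 fold change of -2.76 in K5H2 (adjusted p = 0.114). Rbp2, a retinol-binding protein gene, fell from 3461 ± 651 to 1337 ± 405 in Hmga2-/- (adjusted p = 0.0499) and to 1005 ± 320 in K5H2 (adjusted p = 0.0172). Chil1, a chitinase-like gene, fell from 2169 ± 1213 to 115 ± 49 in Hmga2-/- and to 427 ± 167 in K5H2, and Lgr6 rose from 907 ± 182 to 1955 ± 291 and 1819 ± 410. Xist was listed at 0 in all 9 libraries, and the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were above 0 in all, at 316 to 1993.

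As a hypothesis, glucocorticoid receptor activity could be higher in K5H2 skin, since Zbtb16, Tsc22d3 (1765 ± 782 in WT and 7585 ± 1712 in K5H2), Klf15, Txnip and Glul rose in K5H2 against WT. In Hmga2-/-, Tsc22d3 was at 4830 ± 1618, and these genes and Per1 also had positive log2 fold changes against WT in 6 of 6 (median 1.31), 0 of them past the threshold. The test used 12 other measured glucocorticoid-induced genes. They had a median log2 fold change of 0.51 in K5H2 against WT, 10 of 12 positive (camera p = 1.91e-05; p = 0.00564 with an estimated correlation), and of 0.52 in Hmga2-/- against WT, 11 of 12 positive (camera p = 0.000509; p = 0.0141 with an estimated correlation). None passed singly, and Fkbp5 was at 1672 ± 231, 2838 ± 1956 and 6517 ± 2349 in WT, Hmga2-/- and K5H2 (adjusted p = 0.0567 for K5H2 against WT). Between K5H2 and Hmga2-/- the median was 0.11 with 6 of 12 positive (camera p = 0.377; p = 0.418 with an estimated correlation), so a difference particular to K5H2 was not shown and the hypothesis stays open.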
